A study of Mus musculus with 14 samples.

How the data were processed

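Mouse CD8+ T cells from E.G7 tumors were profiled by RNA-seq in 14 libraries, 2 for each of 7 groups, in 3 experiments: Bcl6+, DN and TIM-3+ TILs (6 libraries), control and Prdm1-overexpressing OT-I cells (4 libraries), and control and Bcl6-overexpressing OT-I cells (4 libraries). Per the labels, total RNA was extracted with Trizol, libraries were made by BGI Genomics, the control and overexpressing OT-I cells were transferred together, and cells were sorted by flow cytometry. The labels do not say which vector the control cells carried, nor whether the strand of a read was used when genes were counted, so counts of overlapping genes may be shared. Apart from strand, reads that match close paralogs such as Hba-a1 and Hba-a2 may be shared between them.

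The deposited files hold, per the file headers, a raw count and an FPKM value (fragments scaled by gene length and library size) for each gene and library. The submitters' processing notes name Bowtie2, Subread, featureCounts, edgeR and DESeq2 for the TIL libraries and HISAT2, featureCounts, RSEM and DESeq2 for the OT-I libraries, with the build mm10; versions and the role of each tool are not given in the sources used here. The deposited counts were whole numbers. They summed to 20185577 and 20644840 in the Bcl6+, 20529410 and 20871012 in the DN, and 22097550 and 22304113 in the TIM-3+ TIL libraries. In the Prdm1 experiment they summed to 18309162 and 19350049 in control and 18381231 and 18372315 in overexpressing cells, and in the Bcl6 experiment to 20256422 and 20575418 in control and 21961117 and 22322079 in overexpressing cells. The tables listed 15319, 19825 and 15216 genes; those of the TIL and Bcl6 experiments listed only genes with a summed count of at least 20. Of these, 15315, 19548 and 15028 were found in the GENCODE M21 annotation, which gave gene positions and GC content. Relative gene length was taken from the ratio of the deposited count to FPKM. Because the aligners differed, and because values were normalized within each experiment, samples were compared only within an experiment.

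The test fixed before the data were examined was limma-trend on log2(FPKM + 1), since the labels named only FPKM. The files also hold raw counts, so the main test became the edgeR 4.0.16 quasi-likelihood test on counts with TMM scaling, in R 4.3.3, and the fixed test was kept as an alternative with limma 3.58.1. Genes with a mean of at least 1 FPKM over the libraries of a fit were tested, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. The 6 TIL libraries shared 1 fit, and each OT-I experiment had its own. SE was the absolute log2 fold change over the square root of the quasi-likelihood F. CPM values were scaled by TMM. Genes at 0 counts in a group were given a lower bound on the fold change from a floor of 3 counts over that group; bounds cover counting error only. The biological coefficient of variation was 0.149 in the TIL, 0.227 in the Prdm1 and 0.164 in the Bcl6 experiment.

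Replicate numbers were not stated to mark a shared animal, so the fits were unpaired.

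Gene lists were fixed before the data were examined and tested with camera on the edgeR counts (preset correlation 0.01) when at least 5 members were measured, with adjustment over the lists of a comparison; camera with an estimated correlation and fry were alternatives. The lists were stem-like progenitor, naive and central memory, terminal exhaustion, inhibitory receptors, cytotoxic effector molecules, killer-cell receptors, effector transcription factors, exhaustion transcription factors, Tfh-associated, chemokines, chemokine and adhesion receptors, tissue residency, cytokine receptors, IL-2 and STAT5 response, TGF-beta response, costimulatory TNF receptors and ligands, proliferation, type I interferon response, glycolysis, fatty acid oxidation and mitochondrial biogenesis, cholesterol synthesis, T cell identity, apoptosis regulators, stress and dissociation, and markers of B cells, macrophages and monocytes, dendritic cells, neutrophils, CD4 and regulatory T cells, erythroid cells, stromal and endothelial cells, and lymphoma and thymocytes. Of these 32 lists, 29 were tested in each TIL comparison and 30 in each OT-I comparison. Members that changed were also counted after adjustment over the list alone. TIL signatures were the 150 genes with the largest fold change in each direction among those called between Bcl6+ and TIM-3+ TILs.

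Genes were named by a rule fixed beforehand: for each comparison, the 10 genes with the largest change in each direction among called genes whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, without predicted gene models and immunoglobulin or T cell receptor segments, then Bcl6, Prdm1, Havcr2, Tcf7 and Slamf6 in every comparison, and up to 4 members of each list with the smallest p. Other genes named were chosen after their values were seen.

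The tests were tried on simulated data. With 200 genes planted at a known change on the fitted spread, edgeR recovered 89, 36 and 73% of 2-fold and 99, 100 and 99% of 4-fold changes in the TIL, Prdm1 and Bcl6 experiments. False calls were 5.53, 8.11 and 5.49% of calls. A planted trend with GC content gave 3245, 726 and 2615 false calls without, and 11, 5 and 4 with, the removal of gene length and GC trends. That trend was of the kind the removal fits, no length trend was planted, and the planted changes were unrelated to GC content. All genes were also given the same spread. The run therefore cannot tell whether the removal strips real change as well. Alternatives were other pseudocounts, filters and scalings, DESeq2 1.42.0, removal of length and GC trends, a replicate block, and leaving out each library in turn. Raw reads were not used here. Some results on single genes are not reported here.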

Results

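RNA was sequenced from CD8+ T cells taken from E.G7 tumors, a mouse lymphoma that descends from the EL4 line, expresses ovalbumin and was grown under the skin. The 14 libraries fell into 7 groups of 2 and 3 experiments. In the first experiment, 3 populations of CD8+ tumor-infiltrating lymphocytes (TILs), labelled Bcl6+, DN and TIM-3+, were sorted on day 21 from Bcl6-RFP reporter mice; the labels do not spell out DN. In the other experiments, OT-I cells, which are CD8+ T cells with a transgenic receptor for ovalbumin, were recovered from E.G7 tumors about 8 days after transfer, either as control and Prdm1-overexpressing cells or as control and Bcl6-overexpressing cells. Total counts per library ranged from 18309162 to 22322079. The labels do not say that replicates came from separate animals, so each p-value measured only the spread between these samples. Levels are given as CPM, counts scaled to a library of 1e6, with the SD of 2 libraries, changes as log2 fold change with the standard error (SE) of the edgeR fit, and adjusted p from edgeR unless another tool is named.

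The transcription factor that names each group was examined first. Bcl6, a transcriptional repressor (ENSMUSG00000022508, mm10 chromosome 16, 23965052 to 23988852, minus strand), measured 416 ± 15 CPM in Bcl6+ TILs, 92.2 ± 2.9 in DN TILs and 16.4 ± 2.4 in TIM-3+ TILs (SD, n = 2). Prdm1, which encodes the repressor Blimp-1 (ENSMUSG00000038151, chromosome 10, 44437177 to 44528501, minus strand), took the opposite order, at 28.9 ± 2.8, 110 ± 12 and 355 ± 7 CPM. Havcr2, the gene of TIM-3 (ENSMUSG00000020399, chromosome 11, 46454935 to 46481255, plus strand), measured 45.8 ± 18, 188 ± 18 and 1329 ± 40 CPM. Tcf7, which encodes the stem-associated factor TCF-1 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014, minus strand), measured 906 ± 64, 548 ± 0.41 and 42.4 ± 9.1 CPM. Slamf6, a surface receptor often used to mark progenitor-like exhausted cells (ENSMUSG00000015314, chromosome 1, 171917515 to 171953170, plus strand), measured 621 ± 4.4, 346 ± 33 and 32.7 ± 9.1 CPM. All 5 are annotated as protein-coding genes. Bcl6-overexpressing OT-I cells held 80.3 ± 19 CPM of Bcl6 against 3.95 ± 0.19 in their controls. Prdm1-overexpressing OT-I cells held 174 ± 26 CPM of Prdm1 against 99.2 ± 14 in theirs. The tables of the 3 experiments were normalized separately, so levels were tested only within an experiment.

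**Figure D1:**
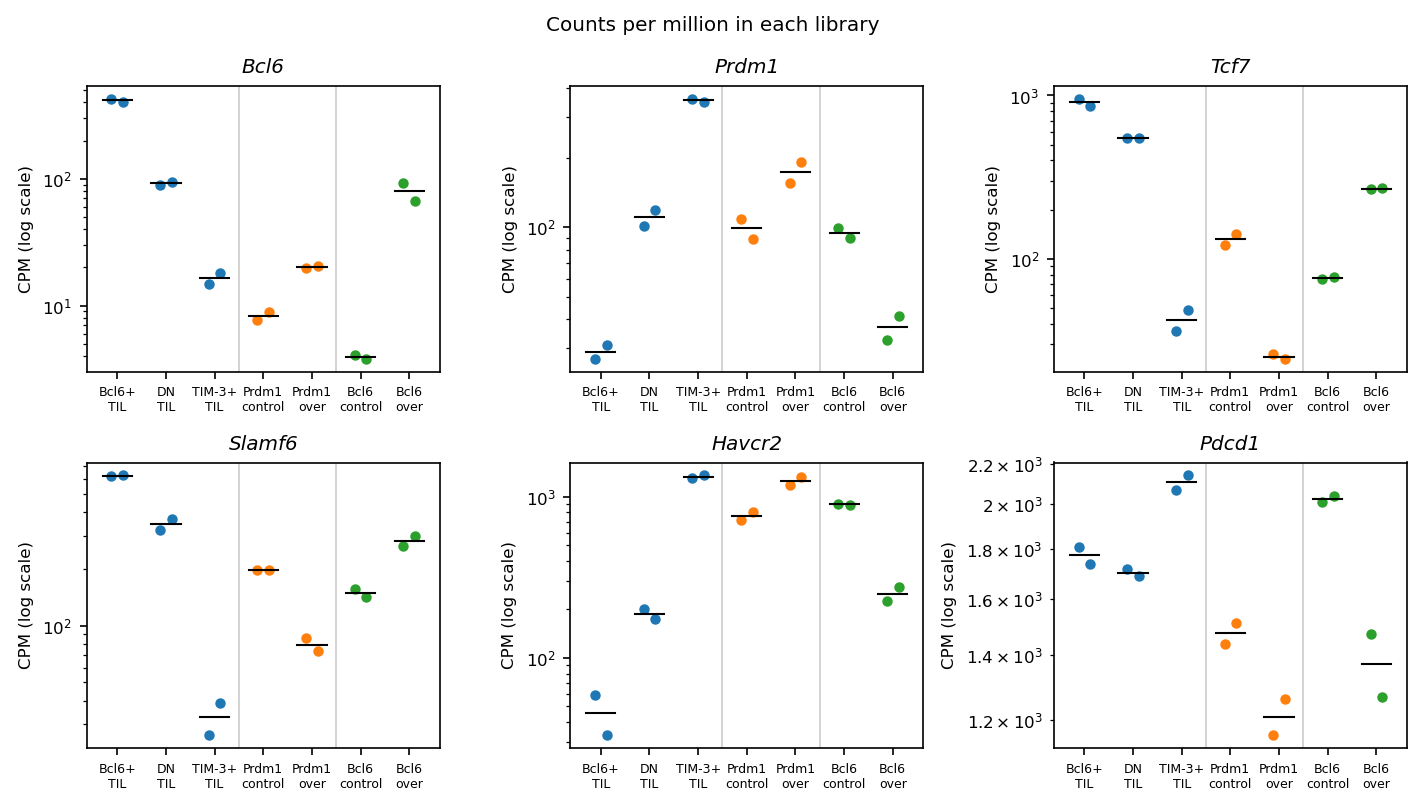
CPM on a log axis for Bcl6, Prdm1, Tcf7, Slamf6, Havcr2 and Pdcd1 in each group; points are the 2 libraries, the line is their mean, and vertical lines separate the 3 experiments. In TILs, Bcl6, Tcf7 and Slamf6 were highest in Bcl6+ cells and Prdm1 and Havcr2 in TIM-3+ cells; Pdcd1 was added to the plot after its values were seen.

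Bcl6+ and TIM-3+ TILs were compared first, to ask how CD8+ TILs that expressed Bcl6 differed from those that carried the exhaustion receptor TIM-3. Bcl6+ cells held 25.3 times as much Bcl6 (log2 fold change 4.66, SE 0.12, adjusted p = 2.2e-12, n = 2) and 21.4 times as much Tcf7 (4.42, SE 0.12, adjusted p = 3.8e-12), with Slamf6 at 4.25 (SE 0.14, adjusted p = 5.4e-11). The group is named for Bcl6 and came from Bcl6-RFP reporter mice, so its Bcl6 difference only checks the sort. TIM-3+ cells held more Havcr2, the marker they were sorted on (log2 fold change -4.86, SE 0.19), and more Prdm1 (-3.61, SE 0.11, adjusted p = 2.6e-11). They also held more of the killing machinery, with Gzmb at 2320 ± 57 against 67.6 ± 20 CPM and Prf1 at 6439 ± 16 against 532 ± 24 CPM. Bcl6+ cells in turn held 250 ± 9 CPM of Cxcr5, the follicle-homing chemokine receptor, against 1.83 ± 1 CPM. Of 9748 genes tested, 3764 differed, 1857 higher and 1907 lower in Bcl6+ cells, and 1508 of them by at least 2-fold, 868 higher and 640 lower. The balance of all calls depended on scaling, at 3530 higher and 1115 lower with TPM and 1532 and 2379 with gene length and GC trends removed.

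Among the lists of genes fixed beforehand, stem-like progenitor genes were mostly higher in Bcl6+ cells: 15 of 16 measured were higher and 1 lower, with the same counts adjusted over the list alone. Examples were Cxcr5 (log2 fold change 7.09) and Tnfsf8 (4.48), and the list passed camera (adjusted p = 6.0e-34; adjusted p = 0.0085 with an estimated correlation). Naive and central memory genes were higher in 12 of 14 and lower in 1, with the same counts adjusted over the list alone (camera adjusted p = 5.0e-17; adjusted p = 0.025 with an estimated correlation). Among them were Ccr7, a lymph node homing receptor (4.01), Il7r, the receptor of interleukin-7 (1.84), and Nsg2 (7.66). Follicular helper (Tfh)-associated genes were higher in 6 of 12 and lower in 2, also adjusted over the list alone, with Pou2af1 at 3.84 (camera adjusted p = 4.4e-10; adjusted p = 0.026 with an estimated correlation).

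Terminal exhaustion genes were lower in 17 of 20 and higher in 2, adjusted over the list alone likewise (camera adjusted p = 6.0e-48; adjusted p = 0.0085 with an estimated correlation). They included Entpd1, the ectonucleotidase CD39 (log2 fold change -4.03), and Cxcr6, a chemokine receptor of tissue T cells (-2.45). Cytotoxic effector molecules were lower in 16 of 20 and higher in 1, with the same counts adjusted over the list alone (camera adjusted p = 3.3e-28; adjusted p = 0.0085 with an estimated correlation), among them Gzmb (-5.10), Prf1 (-3.60) and the gene of interferon-gamma, Ifng (-3.31). All 36 proliferation genes were lower, over all genes and adjusted over the list alone, such as Top2a, at 146 ± 2.4 against 582 ± 24 CPM, and Ccna2 (-2.96), at a camera adjusted p of 1.1e-42 (adjusted p = 0.0085 with an estimated correlation). The chemokine list split. Ccl3 (-5.80), Ccl4 (-5.48) and Ccl5 (-4.76) were lower and Xcl1, which attracts cross-presenting dendritic cells, was higher (2.49); 4 of 9 were lower and 2 higher, or 4 and 3 adjusted over the list alone. Its median was 0.27 while camera placed the list lower (adjusted p = 4.8e-18; adjusted p = 0.023 with an estimated correlation).

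Other lists passed camera with its preset correlation but not with an estimated one. Inhibitory receptors were lower in 11 of 15 and higher in 3, also adjusted over the list alone, with Cd244a at -3.31 and Lag3 at -0.87 (camera adjusted p = 3.1e-07; adjusted p = 0.12 with an estimated correlation). Killer-cell receptors were lower in 7 of 13 and higher in 1, also adjusted over the list alone, with Klrd1 at -1.06 (camera adjusted p = 0.0027; adjusted p = 0.12 with an estimated correlation). T cell identity genes were lower in 13 of 20 and higher in 3, or 13 and 5 adjusted over the list alone, with Cd8a at 1046 ± 24 against 2096 ± 8.9 CPM (camera adjusted p = 0.0062; adjusted p = 0.12 with an estimated correlation). Type I interferon response genes were lower in 12 of 23 and higher in 2, or 13 and 2 adjusted over the list alone, with Ifit2 at -1.23 (camera adjusted p = 0.045; adjusted p = 0.21 with an estimated correlation); without either Bcl6+ library that list no longer passed. Chemokine and adhesion receptors were higher in 11 of 21 and lower in 9, also adjusted over the list alone, with Itgb1 at 2.34 (camera adjusted p = 0.0049; adjusted p = 0.27 with an estimated correlation).

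Markers of other cells moved with these groups. B cell markers, most of which are shared by other antigen-presenting cells, were higher in 5 of 5 in Bcl6+ cells, also adjusted over the list alone (camera adjusted p = 2.5e-11; adjusted p = 0.025 with an estimated correlation), with the invariant chain gene Cd74 at 554 ± 22 against 44.9 ± 2.1 CPM. Macrophage and monocyte markers were higher in 11 of 13 and lower in 1, also adjusted over the list alone (camera adjusted p = 0.0036; adjusted p = 0.21 with an estimated correlation), with Lyz2 at 84.9 ± 4.7 against 21.3 ± 7.3 CPM, while Spp1 was lower (606 ± 31 against 1483 ± 5 CPM). Dendritic cell markers (1 of 6 higher, 2 lower), CD4 and regulatory T cell markers (1 of 7 higher, 2 lower) and erythroid markers (3 of 6 higher, 2 lower) did not pass camera; adjusted over the list alone the counts were 1 and 2, 1 and 2, and 4 and 2. Lists of neutrophil, stromal and endothelial, and lymphoma and thymocyte markers had fewer than 5 measured members and were not tested in TILs; the lymphoma and thymocyte list and the erythroid list were not tested in OT-I cells for the same reason.

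Over all genes tested 38.6% were called between Bcl6+ and TIM-3+ cells, so a count of members near that share says little about a list. Several lists held changed members without passing camera as a set. These were effector transcription factors (5 of 13 higher, 8 lower), such as Id2 at -2.25 and Rora at 2.07, and exhaustion transcription factors (2 of 11 higher, 7 lower), such as Irf4 at -1.91 and Eomes at 0.79. Tissue residency genes (3 of 12 higher, 6 lower), cytokine receptors (10 of 22 higher, 8 lower), TGF-beta response genes (2 of 10 higher, 2 lower) and costimulatory TNF receptors and ligands (7 of 17 higher, 5 lower) did not pass either, nor did apoptosis regulators (5 of 19 higher, 6 lower). All of these counts were the same adjusted over the list alone. Genes of the IL-2 and STAT5 response were higher in 7 of 18 and lower in 7, or 8 and 7 adjusted over the list alone; Il2rb, a receptor chain of interleukin-2, measured -1.46 and Cish, a feedback inhibitor induced by STAT5, -3.46.

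Single genes with the largest differences lay outside most lists. Colq (log2 fold change 10.74), Lipm (9.69) and Fam160a1 (8.47) were among the most increased in Bcl6+ cells. Proc was counted in Bcl6+ cells at 10.4 ± 1.4 CPM and in no TIM-3+ library, which put it at least 141-fold higher, counting error only. In the other direction, Dsc2 (-5.79), Ltf (-5.11) and Chn2 (-5.00) were lower in Bcl6+ cells, and Ripply3, at 0 counts there, was at least 179.7-fold lower.

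Bcl6+ and DN TILs were then compared, to place the Bcl6+ cells against the population labelled DN. Bcl6+ cells held 4.51 times as much Bcl6 (log2 fold change 2.17, SE 0.10, adjusted p = 8.3e-09, n = 2), and more Cxcr5 (2.22), Slamf6 (0.85, SE 0.12, adjusted p = 0.00031) and Tcf7 (0.73, SE 0.10, adjusted p = 0.00019). Here too the Bcl6 difference only checks the sort of the Bcl6+ cells. DN cells held more Prdm1 (-1.93, SE 0.11, adjusted p = 6.0e-08) and Havcr2 (-2.04, SE 0.17, adjusted p = 2.4e-06). DN cells also held more of 2 genes of migrating effector cells, the chemokine receptor gene Ccr2 (86.5 ± 13 against 11.2 ± 3.7 CPM) and the surface marker gene Ly6c2 (266 ± 0.074 against 28.6 ± 2.7 CPM). Of 9748 genes tested, 1383 differed, 633 higher and 750 lower in Bcl6+ cells, and 363 by at least 2-fold, 179 higher and 184 lower. With TPM scaling the balance of all calls turned to more higher than lower. Without DN replicate 1 or 2, 735 or 766 genes differed.

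Cytotoxic effector molecules were lower in Bcl6+ than in DN cells in 15 of 20, also adjusted over the list alone (camera adjusted p = 8.1e-30; adjusted p = 0.017 with an estimated correlation), such as Gzmb (log2 fold change -2.48) and Ifng (-1.59). Chemokines were lower in 5 of 9 and higher in 1, or 6 and 1 adjusted over the list alone (camera adjusted p = 4.9e-29; adjusted p = 0.017 with an estimated correlation), with Ccl5 at -3.23. Terminal exhaustion genes were lower in 11 of 20 and higher in 7, also adjusted over the list alone (camera adjusted p = 6.0e-22; adjusted p = 0.017 with an estimated correlation), with Entpd1 at -2.33. Type I interferon response genes were lower in 16 of 23, or 19 adjusted over the list alone, with none higher (camera adjusted p = 3.6e-12; adjusted p = 0.030 with an estimated correlation). Examples were Ifit3 (-3.18) and Oas3 (-1.33), both antiviral genes. Proliferation genes were lower in 19 of 36, or 25 adjusted over the list alone, with Pcna at -0.64 (camera adjusted p = 2.2e-09; adjusted p = 0.046 with an estimated correlation). Stem-like progenitor genes were higher in 10 of 16 with none lower, or 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.6e-09; adjusted p = 0.038 with an estimated correlation).

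Several further lists passed with the preset correlation alone. Chemokine and adhesion receptors were lower in 10 of 21 and higher in 4, or 12 and 5 adjusted over the list alone (camera adjusted p = 9.1e-06; adjusted p = 0.17 with an estimated correlation). Inhibitory receptors were lower in 7 of 15 and higher in 4, or 8 and 5 adjusted over the list alone, with Cd244a at -2.02 and Tigit at 0.50 (camera adjusted p = 4.0e-05; adjusted p = 0.17 with an estimated correlation). Tfh-associated genes were higher in 5 of 12 and lower in 1, or 6 and 1 adjusted over the list alone, with Sh2d1a at 0.62 (camera adjusted p = 0.00051; adjusted p = 0.12 with an estimated correlation). Killer-cell receptors were lower in 5 of 13 and higher in 2, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0050; adjusted p = 0.17 with an estimated correlation). IL-2 and STAT5 response genes were lower in 7 of 18 and higher in 1, or 8 and 1 adjusted over the list alone, with Cish at -2.81 (camera adjusted p = 0.0082; adjusted p = 0.17 with an estimated correlation). Macrophage and monocyte markers were higher in 5 of 13, or 6 adjusted over the list alone, with Cd68 at 110 ± 22 against 56.7 ± 1.4 CPM (camera adjusted p = 0.010; adjusted p = 0.27 with an estimated correlation). Naive and central memory genes did not pass: 3 of 14 were higher and 2 lower, or 3 and 5 adjusted over the list alone. Among them Ccr7 was higher (0.95), while S1pr1, the receptor that lets T cells leave tissue, was lower (20 ± 2.3 against 89.5 ± 5 CPM).

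TIM-3+ and DN TILs completed the comparison of the sorted populations; the DN libraries are shared with the comparison before it. TIM-3+ cells held 7.07 times as much Havcr2, the marker they were sorted on (log2 fold change 2.82, SE 0.17, adjusted p = 3.9e-08, n = 2), more Prdm1 (1.68, SE 0.10, adjusted p = 4.9e-08) and 5.64 times as much Prf1. They held less Tcf7 (-3.69, SE 0.11, adjusted p = 7.6e-11), Slamf6 (-3.40, SE 0.14, adjusted p = 1.2e-09) and Bcl6 (-2.49, SE 0.11, adjusted p = 2.4e-09). The DN population thus lay between the others in the level of all 5 genes. Of 9748 genes tested, 2745 differed, 1454 higher and 1291 lower in TIM-3+ cells, and 961 by at least 2-fold, 353 higher and 608 lower. The balance of all calls depended on scaling, at 822 higher and 2348 lower with TPM and 869 and 2173 with total counts. Without DN replicate 1 or 2, 1696 or 1734 differed.

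All 36 proliferation genes were higher in TIM-3+ than in DN cells, also adjusted over the list alone, such as Ube2c (2.48) and Top2a (1.59), at a camera adjusted p of 4.3e-47 (adjusted p = 0.0076 with an estimated correlation). Terminal exhaustion genes were higher in 17 of 20 and lower in 1, also adjusted over the list alone, such as Rgs16 (1.40) (camera adjusted p = 5.9e-49; adjusted p = 0.0076 with an estimated correlation). Cytotoxic effector molecules were higher in 13 of 20 and lower in 3, or 13 and 4 adjusted over the list alone, such as Gzmb (2.62) (camera adjusted p = 1.5e-14; adjusted p = 0.018 with an estimated correlation). Stem-like progenitor genes were lower in 14 of 16 and higher in 1, also adjusted over the list alone (camera adjusted p = 9.3e-38; adjusted p = 0.0076 with an estimated correlation). Naive and central memory genes were lower in 12 of 14, or 13 with 1 higher adjusted over the list alone (camera adjusted p = 2.1e-28; adjusted p = 0.018 with an estimated correlation). Id3, a regulator of memory precursors, measured 0.464 ± 0.17 against 15.5 ± 1.5 CPM, and Il7r 41.2 ± 3.8 against 181 ± 3.7 CPM.

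Chemokine and adhesion receptors were lower in 11 of 21 and higher in 5, or 11 and 8 adjusted over the list alone, with Ccr6 at -5.57 (camera adjusted p = 2.1e-15; adjusted p = 0.039 with an estimated correlation). Tfh-associated genes were lower in 6 of 12 and higher in 3, also adjusted over the list alone, with Cxcr5 at -4.87 (camera adjusted p = 4.0e-11; adjusted p = 0.023 with an estimated correlation). Among chemokines, 4 of 9 were higher and 3 lower, also adjusted over the list alone, with Ccl3 at 3.54, Ccl4 at 2.84 and Xcl1 at -1.94; the median was -0.40 although camera placed the list higher (adjusted p = 1.5e-09; adjusted p = 0.028 with an estimated correlation). B cell markers were lower in 5 of 5, also adjusted over the list alone, with Cd74 at 44.9 ± 2.1 against 310 ± 9.7 CPM (camera adjusted p = 2.1e-15; adjusted p = 0.018 with an estimated correlation). Macrophage and monocyte markers were lower in 7 of 13 and higher in 1, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.031; adjusted p = 0.30 with an estimated correlation); Csf1r measured -3.21 and Spp1 1.17.

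Inhibitory receptors (8 of 15 higher, 2 lower) and exhaustion transcription factors (7 of 11 higher, 1 lower) passed camera at adjusted p = 9.6e-06 and 0.013, with the same counts adjusted over the list alone (adjusted p = 0.15 and 0.15 with an estimated correlation). Lag3 measured 1.01, Tox 0.63 and Tox2 2.55. T cell identity genes were higher in 11 of 20 and lower in 2, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.0060; adjusted p = 0.13 with an estimated correlation). Glycolysis genes were higher in 11 of 22 and lower in 3, also adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.30 with an estimated correlation), with Slc16a3, a lactate exporter, at 1.11. Killer-cell receptors were higher in 6 of 13 and lower in 1, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.031; adjusted p = 0.25 with an estimated correlation), and type I interferon genes were lower in 8 of 23 and higher in 2, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.19 with an estimated correlation). The interferon list no longer passed without any 1 of the 4 libraries, nor the killer-cell list without DN replicate 1, nor the macrophage list without DN replicate 2 or TIM-3+ replicate 2.

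Prdm1-overexpressing OT-I cells were compared with their controls to ask which genes follow Prdm1 in T cells of one specificity. Tcf7 fell from 132 ± 15 to 25.2 ± 1.1 CPM (log2 fold change -2.39, SE 0.19, adjusted p = 0.0059, n = 2) and Slamf6 from 197 ± 1.1 to 79.4 ± 8.8 CPM (-1.31, SE 0.17, adjusted p = 0.022). The lymph node homing receptor gene Ccr7 fell with them (-0.97, adjusted p = 0.036). Cxcr6 rose from 1596 ± 100 to 3714 ± 140 CPM (1.22, adjusted p = 0.022), as did Cd244a (1.64, adjusted p = 0.011) and Cd38 (1.40, adjusted p = 0.031), markers of exhausted cells. Prdm1 itself did not pass the test (0.81, SE 0.19, adjusted p = 0.092), nor did Havcr2 (0.73, adjusted p = 0.082) or Bcl6 (20 ± 0.56 against 8.26 ± 0.82 CPM, adjusted p = 0.089).

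Of 9947 genes tested, 135 changed, 115 higher and 20 lower in Prdm1-overexpressing cells, and 120 by at least 2-fold, 104 higher and 16 lower; 1910 genes lay below an unadjusted p of 0.05. With a library left out, the spread came from the pair of the other group. The overexpressing pair differed more than the control pair (chi-square per degree of freedom between replicates 50.7 against 28.1). Most calls were lost with 1 or the other control library left out. More genes were called without overexpressing replicate 1, and the excess of higher calls was not kept there. Such counts cannot tell whether a call rests on the values of 1 library. Tcf7 kept its call without control replicate 1 and not without replicate 2, and Slamf6, Cxcr6 and Cd244a lost theirs either way. DESeq2 called 586 genes and placed Prdm1 (0.77, adjusted p = 0.035) and Bcl6 (1.23, adjusted p = 0.017) past the threshold. Bcl6 also passed in edgeR with TPM scaling (1.22, adjusted p = 0.027) and with gene length and GC trends removed (1.24, adjusted p = 0.044).

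Stem-like progenitor genes leaned down in Prdm1-overexpressing cells: 2 of 14 fell, or 5 with 1 risen adjusted over the list alone (camera adjusted p = 2.0e-05; adjusted p = 0.62 with an estimated correlation). Of naive and central memory genes 2 of 12 fell, or 5 adjusted over the list alone (camera adjusted p = 0.0031; adjusted p = 0.62 with an estimated correlation). Tissue residency genes rose in 3 of 13, or 5 with 1 fallen adjusted over the list alone, with Ccr8 at 1.27 (camera adjusted p = 0.0055; adjusted p = 0.62 with an estimated correlation). No exhaustion transcription factor of 10 passed over all genes, and 4 fell adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.62 with an estimated correlation); Tox measured -0.56 and Eomes -1.12. Tfh-associated genes fell in 1 of 8, or 2 adjusted over the list alone (camera adjusted p = 0.045; adjusted p = 0.62 with an estimated correlation). Of these lists only the stem-like one kept its preset-correlation call with each library left out. The Tfh-associated list lost it without either control library, the exhaustion transcription factors without control replicate 1 or overexpressing replicate 1, the residency list without control replicate 2, and the naive list without overexpressing replicate 1. The Tfh-associated and residency lists also lost it with limma and with quantile normalization. Terminal exhaustion genes did not pass as a set, with 3 of 20 risen, or 5 risen and 3 fallen adjusted over the list alone. No cytotoxic effector molecule passed over all genes, at Prf1 0.74 (adjusted p = 0.083) and Gzmb 0.60 (adjusted p = 0.23), and 2 rose and 1 fell adjusted over the list alone. Il2ra, the high-affinity receptor chain of interleukin-2, rose (1.02, adjusted p = 0.048), Slc2a3, a glucose transporter, rose (1.32, adjusted p = 0.021), and Socs3 fell (-1.11, adjusted p = 0.046).

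Myeloid genes moved in both directions in this experiment. The granule gene Mpo (90 ± 11 against 1.79 ± 1.3 CPM, log2 fold change 5.64) and the cathepsin E gene Ctse (298 ± 17 against 17.2 ± 3.3 CPM, 4.11) rose, as did the protease gene Mmp9 (43.5 ± 9.7 against 0.21 ± 0.23 CPM, 7.68). B cell markers were lower as a set (camera adjusted p = 4.2e-05; adjusted p = 0.62 with an estimated correlation), though none of 5 passed over all genes and 4 fell adjusted over the list alone; Cd74 measured 206 ± 90 against 544 ± 54 CPM. Macrophage and monocyte markers were lower too (camera adjusted p = 0.0026; adjusted p = 0.62 with an estimated correlation), with none of 15 past the test over all genes and 1 risen and 3 fallen adjusted over the list alone; Lyz2 measured 123 ± 53 against 305 ± 28 CPM. The macrophage list lost its call without overexpressing replicate 2. Of neutrophil markers 1 of 5, Mmp9, rose, or 1 risen and 2 fallen adjusted over the list alone, and camera did not call the list (adjusted p = 0.23), whose median of -0.55 and mean of 0.98 differed in sign. Stromal and endothelial markers did not pass in any of 7 members, over all genes or adjusted over the list alone. The Prdm1-overexpressing libraries also held fewer genes at 0 counts (524 and 531) than the controls (1570 and 2177).

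Bcl6-overexpressing OT-I cells were compared with their controls to ask which genes follow Bcl6 in T cells of one specificity. Bcl6 rose 20.3-fold (log2 fold change 4.34, SE 0.26, adjusted p = 2.0e-11, n = 2). With it rose Tcf7, from 76.5 ± 1 to 269 ± 2.3 CPM (1.81, SE 0.17, adjusted p = 2.4e-08), Slamf6 (0.91, SE 0.17, adjusted p = 0.00017), Cxcr5 (4.10) and Id3 (3.74, or 2.84 with gene length and GC trends removed). Prdm1 fell from 94.8 ± 6.3 to 36.9 ± 6.2 CPM (-1.36, SE 0.20, adjusted p = 1.1e-05) and Havcr2 from 900 ± 10 to 250 ± 35 CPM (-1.85, SE 0.18, adjusted p = 2.5e-08). Of 9669 genes tested, 4720 changed, 2459 higher and 2261 lower, and 2329 by at least 2-fold, 1570 higher and 759 lower. The balance of all calls turned with scaling, to more lower than higher with TPM and with quantile normalization.

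The 2 Bcl6-overexpressing libraries stood apart from the controls in their composition. Ribosomal protein genes took 4.77 and 4.31% of their counts against 0.905 and 0.790% in the controls, the repeat-rich genes Gm10800 and Gm10801 took 0.000865 and 0.000685% against 0.194 and 0.190%, and 1900 and 2051 genes had 0 counts against 95 and 69. Fold changes rose with the GC content of the gene (Spearman rho 0.488 across genes) and fell with its length (-0.253). After gene length and GC trends were removed from each library, 3366 of the 4720 calls stood in the same direction and 70 turned. Tcf7 (1.62), Slamf6 (1.19), Prdm1 (-1.16), Havcr2 (-1.70) and Bcl6 (4.22) kept their direction and call.

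**Figure D2:**
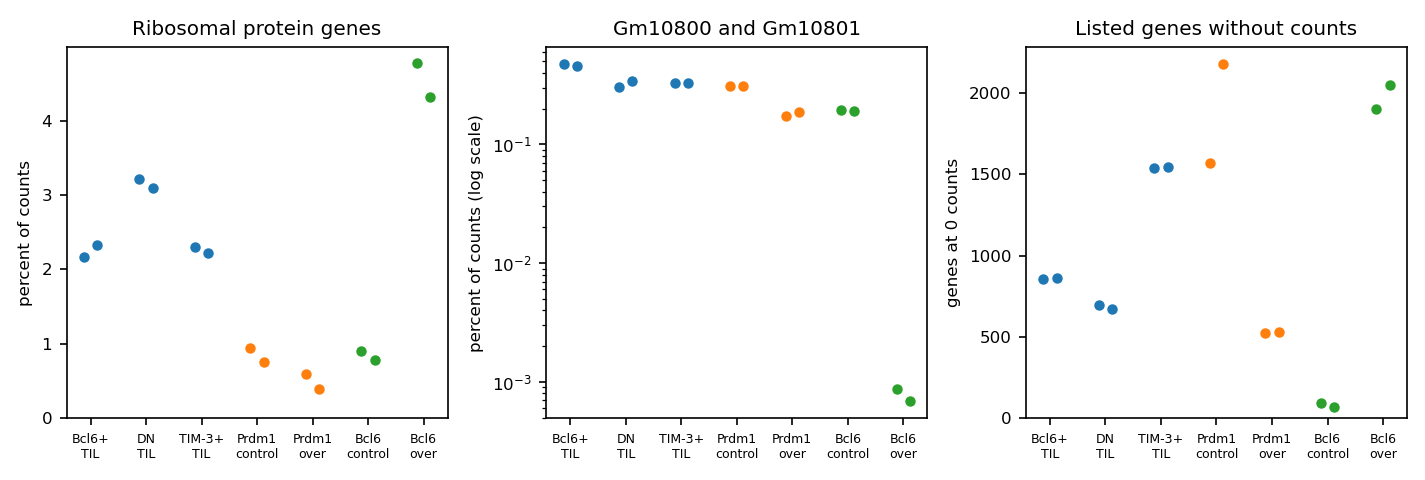
Share of counts from ribosomal protein genes, share from Gm10800 and Gm10801 on a log axis, and number of genes at 0 counts, one point per library by group. The 2 Bcl6-overexpressing libraries lay at 4.77 and 4.31% ribosomal protein counts, above the other 12.

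Stem-like progenitor genes rose in 8 of 15 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.47 with an estimated correlation). Chemokines rose in 7 of 8, also adjusted over the list alone (camera adjusted p = 3.7e-06; adjusted p = 0.47 with an estimated correlation): Xcl1 rose from 28.4 ± 3.9 to 734 ± 24 CPM (log2 fold change 4.69), and Ccl5 (3.43) and Ccl4 (2.37) rose as well. After the length and GC trends were removed these measured 2.53, 1.75 and 0.38. Ccl5 and Ccl4 had gone the other way in TILs, lower in Bcl6+ than in TIM-3+ cells, where camera placed the chemokine list lower. Inhibitory receptors fell in 8 of 15 and rose in 1, also adjusted over the list alone, with Entpd1 at -1.64, Cd244a at -1.62 and Lilrb4a at -1.60 (camera adjusted p = 0.014; adjusted p = 0.47 with an estimated correlation). Proliferation genes fell in 23 of 36 and rose in 3, also adjusted over the list alone, with Kif11 at -1.47 and Rrm1 at -1.27 (camera adjusted p = 0.00097; adjusted p = 0.47 with an estimated correlation).

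Other lists held changed members without passing camera. Over all genes tested 48.8% were called in this comparison, so a count near that share says little about a list. Terminal exhaustion genes fell in 10 of 20 and rose in 5, naive and central memory genes rose in 6 of 13 and fell in 3, and cytotoxic effector molecules rose in 5 of 20 and fell in 6. Adjusted over the list alone these were 10 and 5, 7 and 3, and 5 and 6. Cxcr6 (-2.17) and Serpinb9 (-1.93) fell, Dapl1 (5.27) and Klf2 (2.23) rose, and Gzmb (-1.13) and Prf1 (-1.16) fell; with the length and GC trends removed, Dapl1 measured 3.54, Klf2 0.71 and Gzmb -1.79. Cst7 rose at 1.27 and measured -0.18 (adjusted p = 0.21) once the trends were removed. After that removal, 7 further lists passed camera with its preset correlation, and none of them with an estimated one. The cytotoxic, terminal exhaustion, glycolysis, and stromal and endothelial lists were lower, and the naive and central memory, Tfh-associated and exhaustion transcription factor lists were higher. Exhaustion transcription factors rose in 6 of 10, or 7 adjusted over the list alone, with Nr4a3 at 1.64. In Bcl6+ against TIM-3+ TILs 2 of 11 had been higher and 7 lower. Cytokine receptors fell in 9 of 21 and rose in 2, and glycolysis genes fell in 8 of 22 with none risen, both also adjusted over the list alone, with Il12rb2 at -1.69 and Slc2a3 at -1.47. IL-2 and STAT5 response genes rose in 10 of 19 and fell in 3, also adjusted over the list alone. Cd3d (2.21) and Thy1 (2.97) of the T cell identity list rose while Ptprc fell (-1.04), with 6 of 19 risen and 5 fallen, also adjusted over the list alone; with the trends removed these genes measured 1.60, 2.63 and -0.58.

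Markers of other cells rose in the same libraries. Neutrophil markers rose in 6 of 6, also adjusted over the list alone (camera adjusted p = 0.00014; adjusted p = 0.47 with an estimated correlation); S100a8, an abundant neutrophil protein, was counted at 14.4 ± 3 CPM and in no control library, at least 200-fold higher, counting error only. Macrophage and monocyte markers rose in 12 of 14 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.00014; adjusted p = 0.47 with an estimated correlation), with Lyz2 at 397 ± 40 against 78.3 ± 3.4 CPM. B cell markers rose in 4 of 5, also adjusted over the list alone (camera adjusted p = 0.0055; adjusted p = 0.56 with an estimated correlation), with Cd74 at 502 ± 34 against 141 ± 30 CPM. Removing the length and GC trends took Lyz2 from a log2 fold change of 2.34 to 1.44 and Cd74 from 1.83 to 0.78. Stromal and endothelial markers rose in 1 of 5 and fell in 2, also adjusted over the list alone, and did not pass as a set; Sparc measured 12.6 ± 0.48 CPM in controls and was not counted in Bcl6-overexpressing cells, at least 182-fold lower.

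**Figure D3:**
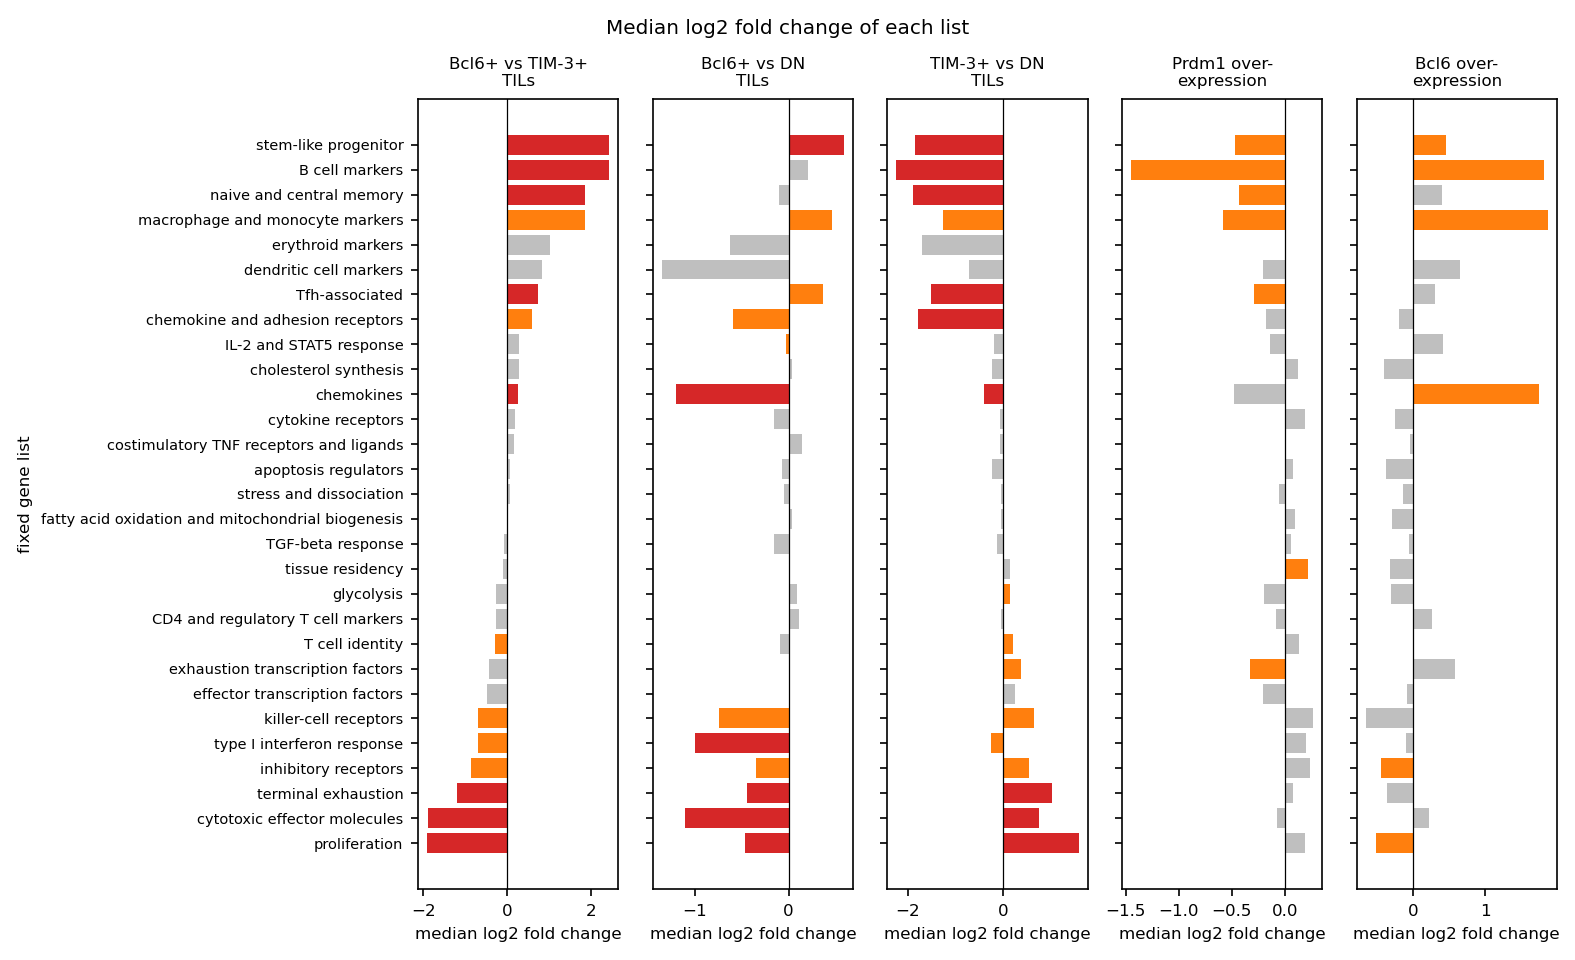
Median log2 fold change of the members of each fixed gene list, 1 panel per comparison; red marks lists past camera with the preset and the estimated correlation, orange those past it with the preset correlation alone, and grey those not past it. Cytotoxic effector molecules and proliferation genes had medians of -1.88 and -1.91 in Bcl6+ against TIM-3+ TILs.

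The TIL difference was then carried to the OT-I cells, whose libraries are separate from the TIL libraries. The 150 genes with the largest difference in each direction between Bcl6+ and TIM-3+ TILs were taken as a pair of signatures. In Prdm1-overexpressing cells the genes higher in Bcl6+ TILs shifted down (55 tested, 2 risen and 4 fallen, median -0.63, camera adjusted p = 2.3e-06; adjusted p = 0.040 with an estimated correlation). Those higher in TIM-3+ TILs shifted up (135 tested, 10 risen and 1 fallen, median 0.36, camera adjusted p = 2.9e-07; adjusted p = 0.040 with an estimated correlation). In Bcl6-overexpressing cells the shifts had the opposite signs. Genes higher in Bcl6+ TILs moved up (61 tested, 37 risen and 3 fallen, median 1.24, camera adjusted p = 2.9e-07; adjusted p = 0.071 with an estimated correlation), and those higher in TIM-3+ TILs moved down (129 tested, 14 risen and 70 fallen, median -0.64, camera adjusted p = 5.8e-06; adjusted p = 0.040 with an estimated correlation). With gene length and GC trends removed these medians were 0.80 and -0.74. With quantile normalization the signature was drawn anew from that fit of the TILs, so its genes differed. The median of the genes higher in Bcl6+ TILs was then smaller still, over more genes tested. That drop mixes a change of genes with a change of normalization. Medians of the B cell marker list were 2.45 in Bcl6+ against TIM-3+ TILs, -1.45 with Prdm1 and 1.82 with Bcl6. Those of the macrophage and monocyte list were 1.87, -0.59 and 1.87, so these lists of other cells moved with the signatures.

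Across all genes the relations between the comparisons were weaker; 3 relations were computed, and genes are not independent replicates. Fold changes of Bcl6+ against TIM-3+ TILs correlated with those of Bcl6 overexpression at Pearson r = 0.16 (Spearman rho 0.14, 9145 genes) and with those of Prdm1 overexpression at r = -0.13 (rho -0.09, 9074 genes). Both overexpression experiments correlated at r = -0.30 (rho -0.47, 9345 genes), while their fold changes trended with GC content in opposite directions (Spearman rho -0.27 with Prdm1 and 0.49 with Bcl6). With length and GC trends removed r was -0.21, and with a library left out it ranged from -0.44 without Prdm1-overexpressing replicate 1 to -0.13 without Prdm1 control replicate 1. Of the genes called in TILs and after Bcl6 overexpression, 702 were lower in both against 447 expected from the counts, and 437 were higher in both against 390, an excess that TPM scaling ended (540 against 548). Another 266 were higher in Bcl6+ TILs and lower after Bcl6 overexpression against 376 expected, and 381 went the reverse way against 463. Of those called in TILs and after Prdm1 overexpression, 13 were higher in both against 15.6 expected, and 5 were lower in both against 3.90. Lower in Bcl6+ TILs and higher after Prdm1 overexpression were 40 against 18.9 expected. That count fell to 1 without Prdm1 control replicate 1, where 0.824 were expected, and to none without control replicate 2, and rose to 111 against 54.2 without overexpressing replicate 1.

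Some genes moved with the TIL difference in all 3 comparisons; those named here were chosen after their values were seen. On the side of Bcl6+ TILs stood 5 genes, higher there, lower with Prdm1 and higher with Bcl6, against 0.761 expected; Tcf7, Slamf6, Socs3 and Atp2a3 were among them. Tcf7 measured 4.42, -2.39 and 1.81 in the 3 comparisons. The count of 5 became 46 with TPM (10.7 expected) and 46 with DESeq2 (9.26 expected). It became 34 with total counts (7.20 expected) and 23 with length and GC trends removed (3.32 expected). On the side of TIM-3+ TILs stood 30 genes against 4.57 expected. That count was 33 with TPM (8.45 expected), 74 with DESeq2 (14.3 expected) and 31 with total counts (4.34 expected). With length and GC trends removed it was 35 (12.1 expected). Expected counts took the 3 comparisons as independent. They may be too low, since 50 genes were higher with Prdm1 and lower with Bcl6 against 22.7 expected. The counts on both sides followed the number of Prdm1 calls. They fell to few or no genes without 1 or the other Prdm1 control library and grew without overexpressing replicate 1. Cxcr6 measured -2.45, 1.22 and -2.17, Cd38 -1.31, 1.40 and -1.01, and F2rl2, a thrombin receptor, -4.42, 2.40 and -1.75. Fgl2 measured -3.29, 1.43 and -2.25, and the interferon-inducible GTPase gene Gbp10 -2.34, 1.78 and -1.73.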

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

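Alternatives were set before the data were examined, except DESeq2, scaling by total counts, and removal of gene length and GC trends, alone or with an estimated correlation, which were chosen after seeing the data, as were all alternatives for overlap counts; limma on log2(FPKM + 1) was the test fixed beforehand and became an alternative only after the data were seen. Where no cause is given, the cause was not tested. No count, named gene or list reversed its call. At a fold change of at least 2, which admits fewer genes by construction, the counts were 1508 (Bcl6+ against TIM-3+), 363 (Bcl6+ against DN), 961 (TIM-3+ against DN) and 2329 (Bcl6 overexpression). Leaving out each library in turn gave 735 to 1191 genes for Bcl6+ against DN and 1696 to 2229 for TIM-3+ against DN. For Prdm1 overexpression the main count of 135 became 44 with no filter, 496 with TPM, 377 with quantile normalization, 275 with median-of-ratios scaling, 75 with no trend, 1659 with a replicate block (only 2 pairs, numbers not stated to mark an animal; same-numbered deviations correlated at 0.028, 0.015 and 0.036 in TILs, 0.279 in the Prdm1 and -0.055 in the Bcl6 experiment; all 135 main calls kept), 586 with DESeq2, 292 with total counts, 347 with length and GC trends removed, and 3 to 643 with a library left out, the lone library taken to vary like the rest. Bcl6 there passed with TPM (1.22), the block (1.28), DESeq2 (1.23) and length and GC removed (1.24). Prdm1 passed with the block (0.81) and DESeq2 (0.77), and ranged from 0.58 to 0.96 with a library left out. The genes higher in Bcl6+ TILs lost their call in Bcl6 overexpression with an estimated correlation (adjusted p = 0.071), and their median of 1.24 became 0.79 with length and GC trends removed in both experiments and 0.49 with quantile normalization, where 108 genes were tested in place of 61. For these medians of 0.79 and 0.49 the signature was drawn anew from the TIL fit of that setting, so its genes could differ from the main ones. The relation of TILs with Prdm1 moved to -0.16 with quantile normalization and ranged from -0.16 to -0.10 with a library left out; that of TILs with Bcl6 moved to 0.10 at a mean of 5 FPKM, 0.14 with quantile normalization and 0.17 with trends removed (0.14 to 0.16 with a library left out); that of both overexpressions ranged from -0.44 to -0.13. Genes lower in Bcl6+ TILs and higher with Prdm1 went from 40 to 107 with DESeq2, 63 with trends removed, 111 without Prdm1-overexpressing replicate 1, and 1 and 0 without control replicates 1 and 2. Genes called in all 3 comparisons on the side of TIM-3+ TILs went from 30 to 74 with DESeq2, 91 without Prdm1-overexpressing replicate 1, and 1 and 0 without the controls; on the side of Bcl6+ TILs they went from 5 to 46 with TPM and with DESeq2, 34 with total counts, 23 with trends removed, 38 and 15 without Prdm1-overexpressing replicates 1 and 2, and 1 and 0 without the controls. Lists called fell with an estimated correlation to 8, 6, 9, 0 and 0 in the 5 comparisons; fry gave 23 for Bcl6+ against TIM-3+, 2 for Prdm1 and 17 for Bcl6 overexpression, no filter gave 13 for Prdm1, and trend removal 14 for Bcl6; trend removal with an estimated correlation gave 8, 6, 7, 0 and 0. Quantile normalization ended 4 of 14 list calls for Bcl6+ against TIM-3+, 2 of 12 for Bcl6+ against DN and 5 of 16 for TIM-3+ against DN. No filter ended 2 of 7 for Bcl6 overexpression. The share of calls that were higher depended on scaling. It was 49.3% for Bcl6+ against TIM-3+, and 76.0% with TPM, 69.3% with total counts and 39.2% with trends removed (median shifts of all genes 0.26, 0.18 and -0.11). It was 53.0% for TIM-3+ against DN, and 25.9%, 28.6% and 64.7% (the first and second with shifts of -0.18 and -0.16); 45.8% for Bcl6+ against DN and 60.5% with TPM; 52.1% for Bcl6 overexpression, and 31.0% with TPM and 41.0% with quantile normalization (shifts -0.34 and -0.15). For Prdm1 overexpression it was 85.2%, and 58.6 to 69.5% under TPM, quantile, median-of-ratios, DESeq2, total counts and trend removal, 60.4% with the block, and 45.9% without overexpressing replicate 1 (295 of 643 calls). The alternative of genes listed in any library did not apply, since the libraries of an experiment list the same genes. Depth limits genes near the filter, where a count of 0 allows up to 3 counts.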

Other observations

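The length and GC prediction was written before its result was seen; the tests of dilution, macrophage RNA and neutrophil RNA were chosen only afterwards, and the macrophage test was first run on Bcl6+ against DN TILs and then moved. The dilution test was later made stricter. The macrophage rule first counted a wide scatter against that source and was replaced after its value was known, since the scatter cannot decide. The neutrophil test, which first counted against that source in Prdm1-overexpressing cells, rested on an assumed ratio to Mpo and was replaced by one on 6 genes whose values were already known.

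Some sterol genes differed between TIM-3+ and the other TILs, but the cholesterol synthesis list passed camera in no TIL comparison (with fry it passed in Bcl6+ and in DN against TIM-3+ cells, adjusted p = 0.031 and 0.046), and between Bcl6+ and DN cells no member of 22 was called. In Bcl6+ against TIM-3+ cells, 7 of 22 cholesterol synthesis genes were higher and 3 lower, also adjusted over the list alone, with Insig1, a sterol-sensing regulator, at 87 ± 0.88 against 38.8 ± 1.4 CPM (SD, n = 2). Against DN cells TIM-3+ cells also held less Insig1 (log2 fold change -1.13), with 2 of 22 higher and 5 lower, also adjusted over the list alone. Glycolysis genes were lower in 13 of 22 and higher in 4 in Bcl6+ against TIM-3+ cells, also adjusted over the list alone, with Slc2a3 at -1.01, and the list did not pass camera (adjusted p = 0.10; 0.48 with an estimated correlation), though it passed with fry (0.010), with limma on log2(FPKM + 1) (0.025) and with length and GC trends removed (0.030). Genes of fatty acid oxidation and mitochondrial biogenesis were higher in 4 of 18 and lower in 5, also adjusted over the list alone, and did not pass as a list either. Over all genes tested 38.6% were called between Bcl6+ and TIM-3+ cells. Stress and dissociation genes, which passed as a list with fry (adjusted p = 0.011) and quantile normalization (0.012) but not in the main test (0.52), split, with 9 of 22 higher and 6 lower, or 9 and 7 adjusted over the list alone: Fos (0.98), Egr2 (1.67) and Dusp1 (0.84) were higher in Bcl6+ cells and Ier2 (-0.75) was lower.

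Some single genes are given for their values alone, chosen after these were seen; the list of apoptosis regulators, which holds Fas and Fasl, did not pass camera (adjusted p = 0.52) but passed with fry (0.021). Bcl6+ cells held more Fas, the death receptor (77.3 ± 4 against 16.1 ± 1.4 CPM), and less of the gene of its ligand, Fasl (111 ± 8.2 against 332 ± 11 CPM), than TIM-3+ cells. They held more Ikzf2, which encodes the factor Helios (421 ± 0.098 against 137 ± 5.4 CPM), and more Lrrc32, which encodes the TGF-beta carrier GARP (76.9 ± 4.9 against 1.02 ± 0.14 CPM). In Bcl6-overexpressing OT-I cells Ikzf2 (1.38) and Lrrc32 (2.29) rose as well, and measured 1.87 and 1.77 once length and GC trends were removed. Fasl fell there (-1.70). Ctse and Mpo rose in both OT-I experiments: Ctse rose from 14.1 to 137 CPM and Mpo from 1.11 to 40.6 CPM with Bcl6, beside the rise with Prdm1; over all genes 18 were higher in both against 22.5 expected, and a test for a shared effect of the vector was dropped, since the labels do not say which vector the control cells carried.

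The TIL signature genes moved in Bcl6-overexpressing libraries whose composition differed from the controls, so a bias by gene length and GC content was tested. After those trends were removed the gap between the medians was 1.54 (SE 0.288, 190 genes, medians 0.80 and -0.74) against 1.88 before, which argues against the bias as the whole cause, though the gap cleared the margin set beforehand only narrowly. Dilution by RNA from other cells stays open: the median of the T cell identity list lay 0.599 above that of the genes higher in TIM-3+ TILs (SE 0.242, 18 genes) and 0.635 above it with the trends removed (SE 0.277), but its members went both ways and their spread of 0.617 and 0.763 exceeded these gaps. The list also cannot register RNA from any other cells that express T cell identity genes themselves. The cause of the different composition stays open too, since RNA quality was not measured here.

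Macrophage and B cell markers were higher in Bcl6+ than in TIM-3+ TILs, although CD8+ cells were sorted. The changes of the macrophage list scattered with a chi-square per degree of freedom of 7.36 over 11 members under 100 CPM in TIM-3+ TILs (105 over all 13), and Spp1 went the other way; in Bcl6+ against DN TILs the same members gave 3.46 and 9.88. A macrophage source would give 1 common factor only if the T cells expressed none of these genes, so the scatter decides nothing and RNA from macrophages stays open. RNA of B cells and expression of some members by the T cells themselves stay open too; no biological explanation was tested.

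Mpo, Ctse and Elane were higher in both kinds of overexpressing cells, although cells were sorted by flow cytometry. In Bcl6-overexpressing cells all 6 of Prtn3, Ctsg, S100a8, S100a9, Camp and Ltf, other genes of the neutrophil lineage, were higher in both libraries than in both controls, the values that RNA from neutrophils and their precursors needs. In Prdm1-overexpressing cells 3 of the 6 were (Prtn3, S100a8 and S100a9), all at low levels, with Prtn3 at 1.33 ± 1.1 against 0.08 ± 0.11 CPM. Over all genes tested, the groups did not overlap, in either direction, in 75.7% with Bcl6 and 51.1% with Prdm1. The 6 genes were also chosen with their values known, so these counts cannot decide. RNA from neutrophils and their precursors stays open in both experiments. Whether Mpo and Ctse came from the T cells stays open too, and no biological explanation was tested.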
